A study of Saccharomyces cerevisiae with 73 samples.

How the data were processed

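The data were 73 two-colour arrays of yeast cells that had been grown in complete dextrose medium, filtered, washed and shifted to 1 of 13 media. Each array compared cells 15, 30, 60, 120 or 240 min after the shift (Cy5) with cells from before it (Cy3, t = 0), with no dye swaps, so a dye effect of a gene adds to its value against t = 0 and to no comparison between media. The arrays cover 65 combinations of culture and time, with 8 repeat arrays that were averaged with their partners. Of the repeats, 2 carry the note ojgrid, which is not explained. The labels of SEtOH+aa disagree on which time point was repeated, and the titles (60 and 120 min) were followed.

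The values deposited by the authors were read as log10 ratios of shifted over t = 0 cells. The log base, the direction and the normalization are not stated with the deposited table. The values are centred near 0 (array medians between -0.17 and 0.06 on the log2 scale) and end at exactly 2 in either direction, which on a log10 scale is 100-fold. They were multiplied by 3.32 to give log2 ratios and not normalized further. If the base was 2, every log2 value printed here would be 3.32 times smaller, with the same p values and directions for genes and lists. The counts at 2-fold thresholds and the genes entering the test of pathway order would change, and the limit would be 4-fold. If the ratios were the other way round, every difference would change sign. Of the values 11677 (2.56%) were missing, 233 were at the upper limit and 280 at the lower limit, and values at a limit were kept.

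The table has 6256 probes, of which 5568 had 1 gene symbol, 0 had several and 688 had none. The identifiers of 5563 of them were found in the R64 gene table, which was used for names only. Probes of the same gene were averaged (29 genes had more than 1), leaving 5538 genes. Probes without a gene were left out of the comparisons and tested as an alternative. Per array, 4954 to 6254 probes had a value (median 6220). Signal and background intensities were not used here, so precision was taken from the cultures, and the number of arrays and of cultures limits it.

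Each medium was 1 culture, and the culture was the replicate: a culture's value was the mean over its 5 time points, for genes with a value at 3 or more time points in every culture. Cultures of different media could not be paired because each medium was 1 culture, and change over time was tested within cultures. The 11 cultures with all or no amino acids were fitted in limma 3.58.1 (R 4.3.3) with terms for carbon source, amino acids and inositol (lmFit and eBayes), and all 13 with amino acids in 4 levels for the partial media, with amino acids acting alike in every carbon source. Interactions were tested in the same way, by a moderated F test for carbon source by amino acids. The change from 15 to 240 min was tested on the difference within each culture, and the shifted cells on the culture means against 0. P values were 2-sided and adjusted over genes by the method of Benjamini and Hochberg, with a threshold of 0.05. The same fits were made at single time points. Contrasts within 1 carbon source, or with or without amino acids, were added after seeing the data.

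Gene lists (27, with 345 members, 338 of them with a probe) were tested with camera at a preset correlation between genes of 0.01 and at an estimated correlation. They were also tested with fry, for movement one way and for movement in either direction. Results of fry are not given here. Members of the lists with no probe were not analysed here. The tests were adjusted over lists within a comparison, and members past the threshold were counted over all genes and adjusted over the list alone. Of the lists described, the sulfur and methionine list in ethanol held with an estimated correlation. The order of steps in 9 amino acid pathways was set against the time of half-maximal rise, found by linear interpolation for genes with a maximum of 1 log2 unit or more, in pathways with 4 or more such genes in a culture. The mean Spearman rho was tested by 1e+05 permutations of the step order within pathways. Counts of genes at 2-fold or more per array are descriptive.

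The named genes were the 8 largest positive and 8 largest negative differences past the threshold for ethanol or galactose against dextrose, amino acids, inositol and time, and 5 and 5 for other comparisons. To these were added up to 4 members of each list described with the largest differences, the genes GAL1, GAL7, GAL10, INO1, ADE2, ADH2 and ARG1 where they bear on a comparison, and the genes of the ordered pathways. Not every gene so chosen is named. The comparisons, lists, this rule and most alternatives were fixed before the data were examined.

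The alternatives were centring each array on its median, quantile normalization, genes with a value on every array, first arrays of repeats, eBayes with trend and robust, a further 2-fold threshold, early or late time points, 9 cultures with the same 3 amino acid and inositol combinations in every carbon source, all arrays with culture as a random block, and each culture left out in turn. Chosen after seeing the data were, for the partial media, 1 mean per carbon source and amino acid setting, and for all comparisons values at the limit taken as missing, probes without a gene included, and the SEtOH+aa arrays with doubtful labels left out. The fits were tested on simulated data with 200 changed genes in 5 runs: of changes of 1 and 2 log2 units, 74.7% and 95.3% were found for ethanol against dextrose, 83.5% and 98.0% for amino acids, 23.6% and 78.8% between the partial media, and 0% and 88.0% for the interaction of carbon source and amino acids. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in python 3.11.15.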

Results

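Transcript levels of the budding yeast strain KCN118, an S288C ade2 strain of mating type alpha, were measured on 73 arrays after cells were moved from a complete dextrose medium into 1 of 13 media. The media differed in carbon source (dextrose, ethanol or galactose), in amino acids and in inositol. Each medium was 1 culture, sampled 15, 30, 60, 120 and 240 min after the shift, and every array set the shifted cells (Cy5) against the cells from before the shift (Cy3, t = 0). There were 5 dextrose, 4 ethanol and 4 galactose cultures. Of the dextrose media, 1 held only the amino acids LIVWHM and 1 only ARNCQGKPSDEFTY, in letter code. The other 11 cultures had either no amino acids (6 cultures) or all of them (5 cultures), and 1 of these 5, SD+aa, held dextrose. Between 4954 and 6254 probes had a value per array (median 6220), and 5538 genes were analysed. The number of arrays and of cultures limits the precision. All values are log2 ratios computed from deposited values read as log10. The base and the direction are not stated. If the base was 2, every log2 value here would be 3.32 times smaller, with the same p values and directions for genes and lists. The counts at 2-fold thresholds and the genes entering the test of pathway order would change, and the limit below would be 4-fold. If the ratios were the other way round, every difference would change sign. Deposited values end at 100-fold in either direction, so the means of BTN2, HSP26, HSP30, SSA4, HSP42, TMA10, RGI1, HSP12, MEP2 and PUT1, which often reached that limit, understate their changes.

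The time at which most genes had moved differed between carbon sources. In SD, the dextrose medium without amino acids and inositol, 1739 genes were 2-fold or more from t = 0 at 15 min and 154 at 240 min. In SD+ino the count went from 1648 to 203, with LIVWHM from 1463 to 233 and with ARNCQGKPSDEFTY from 1360 to 100. In SD+aa, which lacked only inositol, it was 164 at 15 min and 1 at 240 min. The ethanol cultures began with 91 to 239 genes at 15 min and reached 2049 to 2338 at 240 min. The galactose cultures went from 121 to 279 genes to between 1427 in Sgal+ino and 2620 in Sgal+aa+ino. These counts describe single cultures and carry no test.

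**Figure D1:**
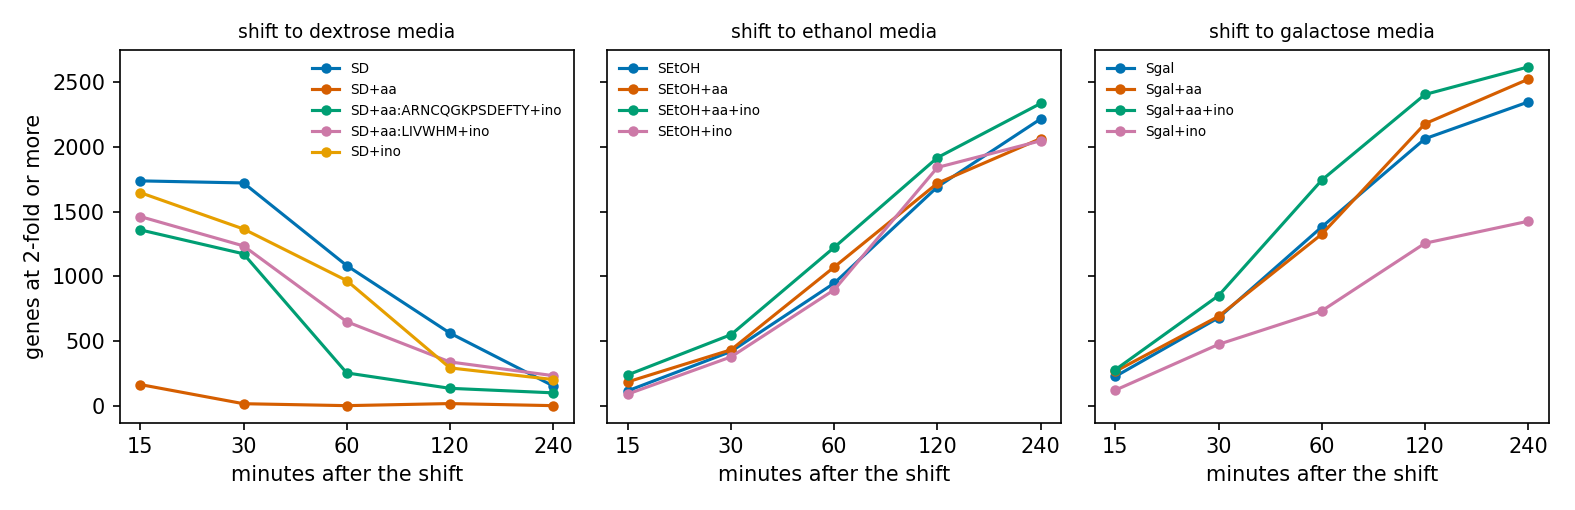
Number of genes at 2-fold or more from t = 0 (y axis) against minutes after the shift (x axis), with 1 line per culture and 1 panel per carbon source. In SD the count fell from 1739 to 154 while in SEtOH it rose from 116 to 2218.

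Compared with t = 0, stress genes were higher and genes for making ribosomes were lower over the 13 cultures. The mean log2 ratio was 4.39 ± 0.54 (SE, n = 13 cultures) for TMA10, 4.26 ± 0.20 for HSP12, 4.05 ± 0.33 for AIM17, 4.03 ± 0.57 for HSP42 and 3.67 ± 0.55 for RGI1. It was -2.22 ± 0.17 for NSR1, -2.14 ± 0.34 for AQR1, -2.12 ± 0.24 for YGR079W and -2.01 ± 0.21 for INA1. All 16 tested genes of the environmental stress response list were higher (16 adjusted over the list alone), with a median of 2.84. All 26 ribosome biogenesis genes were lower (26 adjusted over the list alone), with a median of -1.39. In limma, 3849 of 5164 genes differed from t = 0, 1757 higher and 2092 lower. Both lists passed with camera at a preset correlation (adjusted p = 7.11e-08 for each), with adjusted p = 0.586 for each with an estimated correlation.

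**Figure D2:**
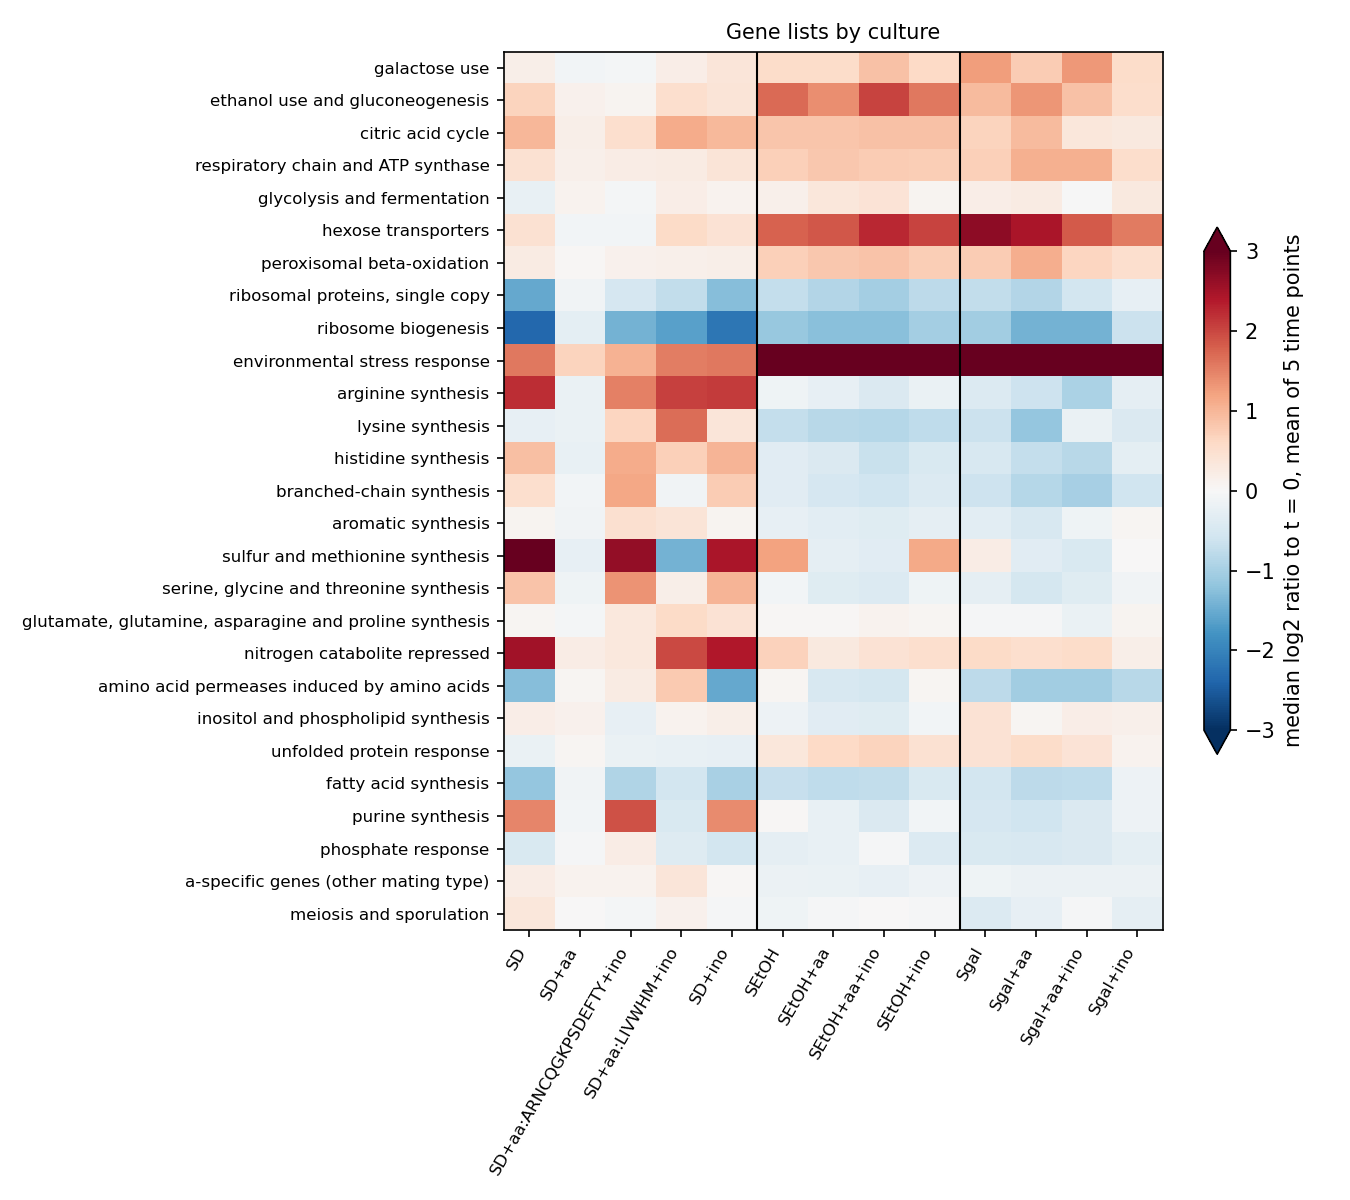
Median log2 ratio to t = 0 (colour, mean of 5 time points, colours end at 3 in either direction) of each gene list (rows) in each culture (columns, grouped by carbon source). The environmental stress response list is high in every ethanol and galactose culture, and the arginine synthesis list is at -0.20 in SD+aa and at 1.52 or more in the other dextrose cultures.

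To see what replacing dextrose by ethanol changed, the 4 ethanol cultures were compared with the 3 dextrose cultures, with additive terms for amino acids and inositol. No dextrose culture had both all amino acids and inositol, and the amino acid effect differed between carbon sources for 1057 of 5340 genes. The 8 largest differences toward ethanol were BTN2, with a log2 difference of 6.83 ± 0.22 (SE), HSP30 (6.09 ± 0.26), SSA4 (5.70 ± 0.16), HSP26 (5.53 ± 0.20), TMA10 (4.68), HSP42 (4.58), HSP104 (4.56 ± 0.19) and RGI1 (4.42). MEP2 was lower by the largest amount (-4.05 ± 1.00, adjusted p = 0.0157), followed by GAP1 (-3.08), SUL1 (-3.01), ILV5 (-3.01 ± 0.16), DAL5 (-2.64), AQR1 (-2.34), OAC1 (-2.29) and ADE17 (-2.28). Of these, MEP2, GAP1, SUL1, DAL5 and the purine gene ADE17 were higher without amino acids in dextrose (below), and SD and SD+ino had none. Their differences are therefore not those of carbon source alone. The hexose transporters HXT6 (3.12) and HXT7 (2.75) and the ethanol use genes ACS1 (2.11), JEN1 (1.68) and ICL1 (1.60) were higher in the mean over time, but at 15 and 30 min ACS1 was at -0.060 (adjusted p = 0.783), JEN1 at -0.60 (adjusted p = 0.145) and ICL1 at 0.40 (adjusted p = 0.164). GAL1 was higher by 0.87 (95% interval 0.47 to 1.28) and GAL7 by 1.43 (0.82 to 2.04), while GAL10 was at -0.13 (-0.44 to 0.17). Of 19 tested stress response genes 9 were higher (11 adjusted over the list alone), and of 13 ethanol use genes 9 were (9 adjusted over the list alone). Of 11 branched-chain synthesis genes 7 were lower (9 adjusted over the list alone), as were 6 of 6 arginine genes (6 adjusted over the list alone) and 7 of 8 purine genes (8 adjusted over the list alone). Among cultures with all amino acids, a contrast chosen after seeing the data, only 5 of 11 branched-chain genes were lower and 1 higher (5 and 1 adjusted over the list alone), with 1 of 6 arginine and 2 of 8 purine genes lower (0 adjusted over the list alone for both). In limma 1662 of 5340 genes differed, 701 higher and 961 lower, and at single time points the count was 1990 at 15 min, 742 at 30 min and 3063 at 240 min. The stress list had a camera adjusted p of 5.33e-08, with adjusted p = 0.416 with an estimated correlation. Without the SEtOH culture 979 genes differed, without SEtOH+aa 1093, and with each array centred on its median 58.7% rather than 42.2% of the genes that differed were higher.

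The shift to galactose was tested in 4 cultures against the same 3 dextrose cultures. The 8 largest differences toward galactose began with a log2 difference of 6.62 ± 0.22 (SE) for BTN2, 6.03 ± 0.26 for HSP30, 5.41 ± 0.20 for HSP26, 5.36 ± 0.16 for SSA4, 4.69 ± 0.40 for TMA10 and 4.35 ± 0.24 for HSP42. FES1 (4.28 ± 0.15) and ZPR1 (4.28 ± 0.39) came next. MEP2 (-3.85), SUL1 (-3.80), ILV5 (-3.62), GAP1 (-3.32), MET5 (-2.77), ARG3 (-2.71), ADE17 (-2.63) and DAL5 (-2.50) were lower, with standard errors from 0.16 to 1.00. As in the ethanol comparison, MEP2, SUL1, GAP1, DAL5 and the purine gene ADE17 also depended on amino acids in dextrose. Their differences are therefore not those of carbon source alone. MET5 and ARG3 belong to lists that depended on them too. Of the 20 sulfur and methionine genes, 19 were higher without amino acids in dextrose. The arginine list was at -0.20 in SD+aa and at 1.52 or more in the other dextrose cultures. GAL1 was higher by 1.06 (95% interval 0.65 to 1.46), GAL7 by 1.12 (0.51 to 1.73) and INO1 by 1.17 (0.84 to 1.49), while GAL10 was at 0.06 (-0.24 to 0.37). Of 19 stress response genes 11 were higher (12 adjusted over the list alone), and of 30 respiratory chain genes 13 were (13 adjusted over the list alone). Of 11 branched-chain genes 10 were lower (10 adjusted over the list alone), as were 14 of 20 sulfur and methionine genes (15 adjusted over the list alone). With all amino acids these were 8 of 11 and 3 of 20 (8 and 3 adjusted over the list alone), with 1 gene of each list higher (1 adjusted over the list alone for both). In limma 2212 of 5340 genes differed, 964 higher and 1248 lower. The branched-chain list had a camera adjusted p of 0.000244, with adjusted p = 0.703 with an estimated correlation. Without the Sgal culture 1432 genes differed, and with each array centred on its median 54.0% rather than 43.6% of the genes that differed were higher.

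Between ethanol and galactose, 4 cultures each, the genes that differed most were CIN5 (-3.63 ± 0.29, SE), GPX2 (-2.68 ± 0.37), TSA2 (-2.13), YCR102C (-2.09) and YLR108C (-2.07 ± 0.15), all lower in ethanol. PIC2 (1.76 ± 0.34), YNL195C (1.71), YNR068C (1.44), GPM2 (1.43) and ECL1 (1.35) were higher in ethanol, and so were ACS1 (1.33 ± 0.21, adjusted p = 0.0229) and ICL1 (1.17 ± 0.24, adjusted p = 0.0356). No gene of the galactose use list passed in the mean over time: the difference was -0.19 (95% interval -0.55 to 0.18) for GAL1, 0.31 (-0.25 to 0.86) for GAL7 and -0.20 (-0.47 to 0.08) for GAL10. At 240 min alone, looked at after seeing the data, GAL1 was lower in ethanol by -0.75 ± 0.22 (adjusted p = 0.0494), with adjusted p = 0.0503 with each array centred and a difference of -0.39 (adjusted p = 0.284) with quantile normalization. No other gene of the list passed then, with GAL2 at -0.98 (adjusted p = 0.0592) and GAL3 at 0.61 (adjusted p = 0.168). Of 13 ethanol use genes 2 were higher in ethanol (5 adjusted over the list alone), with a camera adjusted p of 0.000436 and adjusted p = 0.888 with an estimated correlation. In limma 201 of 5340 genes differed, 110 higher in ethanol and 91 lower. At 15 min limma called 0 genes and at 240 min 678. The total was 2 genes without SEtOH+aa+ino or SEtOH+ino, 8 without SEtOH, 10 without SEtOH+aa, 13 without Sgal, 60 without Sgal+aa+ino, 94 without Sgal+ino, 111 without SD+ino and 852 without SD+aa.

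Leaving out all amino acids was compared with supplying all of them in 6 and 5 cultures, with additive terms for carbon source and inositol. The 8 largest differences were all higher without amino acids: the log2 difference was 2.55 ± 0.33 (SE) for MET2, 1.98 ± 0.20 for MHT1, 1.88 ± 0.26 for MUP3, 1.83 ± 0.27 for MMP1, 1.55 ± 0.20 for MET6, 1.43 ± 0.16 for OPT1, 1.43 ± 0.17 for SAM3 and 1.11 ± 0.16 for DUG3. Of 20 sulfur and methionine genes 5 were higher (20 adjusted over the list alone), with a camera adjusted p of 6.59e-28 and adjusted p = 0.234 with an estimated correlation. In limma 14 of 5340 genes were higher and 0 lower, with 0 genes left without SEtOH, without SEtOH+aa, without SEtOH+aa+ino or without Sgal. The count was 3 without SEtOH+ino, 4 without SD+ino, 6 without SD, 7 without Sgal+aa+ino and 78 without SD+aa. Quantile normalization left 1 gene, a lower one.

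The effect of amino acids differed between carbon sources. In dextrose without amino acids, MEP2 was higher by 5.89 ± 0.25 (SE, 2 cultures against 1), SUL1 by 5.56 ± 0.23, GAP1 by 5.32 ± 0.26, MET3 by 4.40 ± 0.19, DAL5 by 4.22 ± 0.28, ARG1 by 2.75 and ADE2 by 1.79. TAT1 (-2.82), RPA135 (-2.76), HCA4 (-2.74), NOP7 (-2.71) and IMD4 (-2.71) were lower. In ethanol, MET2 (2.86 ± 0.17), MMP1 (2.30), MUP3 (2.26), MUP1 (2.24) and MHT1 (2.23) were higher and ARO10 (-1.45 ± 0.21), YDL012C (-0.95) and AHP1 (-0.84) lower, in 2 cultures against 2. In galactose, MET2 (1.44 ± 0.17), OPT1 (1.31), MHT1 (1.31) and MET6 (0.98) were higher and ARO9 (-2.79 ± 0.31), ARO10 (-1.90) and IGD1 (-1.16) lower. The effect in dextrose exceeded that in ethanol by 5.09 ± 0.31 for MEP2 and by 4.74 ± 0.33 for GAP1, and that in galactose by 5.87 ± 0.31 and 5.48 ± 0.33. Without amino acids in dextrose, 25 of 26 ribosome biogenesis genes were lower (25 adjusted over the list alone), 11 of 13 nitrogen catabolite repressed genes higher and 1 lower (11 and 1 adjusted over the list alone), 8 of 8 purine genes higher (8 adjusted over the list alone) and 19 of 20 sulfur and methionine genes higher (19 adjusted over the list alone). The sulfur and methionine list had 17 of 20 genes higher in ethanol (20 adjusted over the list alone) and 3 of 20 in galactose (15 adjusted over the list alone). Its camera adjusted p in ethanol was 1.84e-59, and 0.0137 with an estimated correlation.

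**Figure D3:**
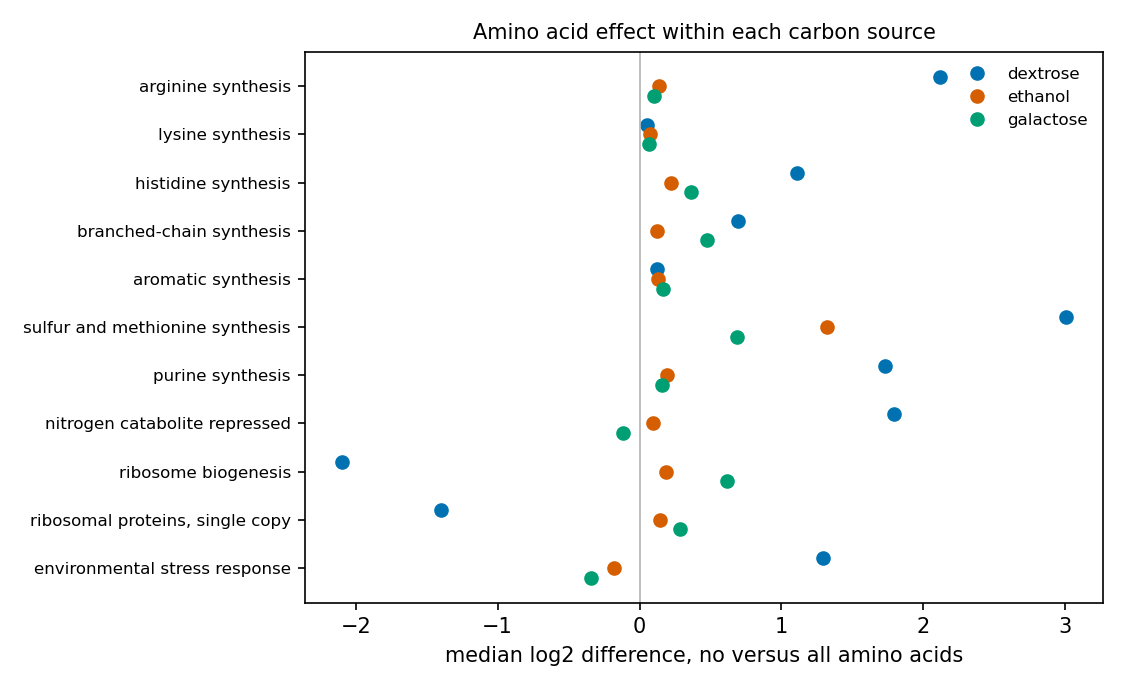
Median log2 difference between no and all amino acids (x axis) of 11 gene lists (y axis), with 1 point per carbon source. The ribosome biogenesis list was at -2.10 in dextrose, 0.19 in ethanol and 0.61 in galactose.

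These within-carbon contrasts were chosen after seeing the data, from a limma model with the interaction of carbon source and amino acids, in which 1057 of 5340 genes had an effect of amino acids that differed between carbon sources. Amino acids changed 1371 genes in dextrose (648 higher without them), 34 in ethanol (31 higher) and 7 in galactose (4 higher). Between dextrose and ethanol the effect differed for 974 genes and between dextrose and galactose for 1391. These counts are for the mean over time: in dextrose the count fell from 2868 genes at 15 min to 36 at 240 min, while it rose from 0 to 34 in ethanol and from 0 to 10 in galactose. In galactose 506 genes passed without the Sgal+aa culture, 4 without SD or SD+ino, 1 without Sgal and 0 without Sgal+aa+ino or Sgal+ino. In ethanol 13 passed without SEtOH+ino. The interaction had 677 genes without SD, and the difference between dextrose and galactose 817 without Sgal+ino. All dextrose values rest on SD+aa as the only culture with all amino acids, so variation between such cultures was not measured and the standard errors and calls borrow it from the other media.

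Inositol was left out in 6 cultures and supplied in 5. INO1 differed by 0.23 (95% interval -0.03 to 0.49), the lysine synthesis list had a median of -0.37, and no list member passed over all genes (1 lysine gene, lower, adjusted over the list alone). In limma 0 of 5340 genes differed, 95 having an unadjusted p under 0.05. On simulated changes of 1 log2 unit in 200 of these 5340 genes, 84.6% were found, and a change of fewer genes was not simulated. The lysine list had a camera adjusted p of 0.00023, with adjusted p = 0.948 with an estimated correlation. No gene had an effect of amino acids that differed with inositol in limma (0 of 5340, with 204 at an unadjusted p under 0.05), but 18 did without SEtOH+aa+ino and 3 without Sgal+aa+ino.

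Media with part of the amino acids held dextrose, with 1 culture of each, so variation between cultures of these media was not measured and all standard errors and calls rest on the other media. They were compared in a fit of all 13 cultures in which amino acids acted alike in every carbon source, so no amino acids stood for 6 cultures, 4 of them in ethanol or galactose. Methionine and purine genes were lower with LIVWHM than with ARNCQGKPSDEFTY: the log2 difference was -5.84 ± 1.15 (SE) for MET3, -5.80 ± 1.00 for MET14, -5.35 ± 0.99 for ADE17, -4.98 ± 0.47 for MHT1 and -4.95 ± 0.87 for MET5. The LIVWHM mean of MHT1 includes 1 value at the lower limit, at 240 min, while its other times had a median log2 ratio of -2.77. That value also enters the difference of MHT1 from no amino acids given below. PDH1 (3.49 ± 0.66), PTR2 (3.31 ± 0.41), DUR3 (2.91), CRC1 (2.85) and OPT2 (2.47) were higher with LIVWHM. The branched-chain genes LEU1 (-3.39) and BAT1 (-2.66) were lower, and INO1 was higher by 1.43 (95% interval 0.84 to 2.02), its value with ARNCQGKPSDEFTY including 1 at the lower limit, and by 0.16 with that value missing. Of 20 sulfur and methionine genes 15 were lower (20 adjusted over the list alone), and of 8 purine genes 4 were (8 adjusted over the list alone), with camera adjusted p values of 2.34e-35 and 3.4e-13 that became adjusted p = 0.187 for both with an estimated correlation. With LIVWHM, ARO10 was higher than without amino acids by 3.59 ± 0.53, AGP1 by 3.37 ± 0.38, PTR2 by 3.11, CAR1 by 2.19 and BOP2 by 2.14. MET3 (-5.58 ± 1.00), MET14 (-5.51), MHT1 (-4.88 ± 0.41), MET6 (-4.66) and ADE17 (-4.44) were lower. With ARNCQGKPSDEFTY, ARO10 was higher than without amino acids by 3.71 ± 0.53. In limma, 130 of 5164 genes differed between the 2 partial media (29 higher with LIVWHM and 101 lower), 122 between LIVWHM and no amino acids (17 higher, 105 lower) and 12 between ARNCQGKPSDEFTY and none (2 higher, 10 lower). With the values at the limit taken as missing these counts were 40, 34 and 0. With quantile normalization they were 134 (53 higher, 81 lower), 88 (41 higher, 47 lower) and 11 (9 higher, 2 lower), of which 65, 44 and 2 were among the genes reported. A fit with 1 mean per carbon source and amino acid setting, chosen after seeing the data, sets the partial media against the 2 dextrose cultures without amino acids. It gave 310, 374 and 188 genes, including all those reported, and 204, 291 and 170 with the values at the limit missing. Between ARNCQGKPSDEFTY and none, more of these genes were higher than lower, unlike in the reported fit. Without SD+aa the reported counts became 308, 384 and 202. Without SD+ino 70 genes passed between LIVWHM and none. Between ARNCQGKPSDEFTY and none, 0 passed without SD+ino or SEtOH+aa, 3 without SEtOH, SEtOH+ino, SEtOH+aa+ino or Sgal, 5 without SD and 19 without the LIVWHM culture.

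From 15 to 240 min ribosome biogenesis genes moved in opposite directions in dextrose and in the other carbon sources. In the 5 dextrose cultures, HCA4 rose by 4.12 ± 0.57 (SE), LTV1 by 3.99 ± 0.49 and URA7 by 3.79 ± 0.49, while MSC1 (-3.86 ± 0.22), HSP12 (-3.82 ± 0.31) and TMA10 (-3.79 ± 0.49) fell. In the 4 ethanol cultures, JEN1 rose by 5.71 ± 0.51, HSP12 by 5.70 ± 0.35 and YAT2 by 5.50 ± 0.46, while PPT1 (-2.94), NOG1 (-2.94) and PMA1 (-2.89 ± 0.28) fell. In the 4 galactose cultures, CTA1 rose by 5.00 ± 0.30, HSP12 by 4.54 ± 0.35 and HXK1 by 4.09 ± 0.36, while PMA1 (-2.80 ± 0.28), PPT1 (-2.75) and UTP9 (-2.63) fell. The change of HSP12 was larger than in dextrose by 9.51 ± 0.46 in ethanol and by 8.36 ± 0.46 in galactose. All 24 ribosome biogenesis genes tested rose in dextrose (24 adjusted over the list alone) and all 24 fell in ethanol and in galactose (24 adjusted over the list alone in each). Of 15 stress response genes, 14 fell in dextrose (14 adjusted over the list alone) and 15 rose in ethanol and in galactose (15 adjusted over the list alone in each), with camera adjusted p values of 2.7e-08, 2.14e-06 and 3.94e-06 that became 0.709, 0.332 and 0.463 with an estimated correlation. With quantile normalization, which gives every array the same spread of ratios and so removes any growth of the response, the stress list median was -0.14 in ethanol and -0.32 in galactose. The camera adjusted p values were 0.822 and 0.839.

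Over all 13 cultures limma called 462 of 4638 genes between 240 and 15 min, 166 higher and 296 lower. CTA1 (2.96 ± 0.65, SE), BAT2 (2.07), SSA4 (1.92), CTR1 (1.86), MEP2 (1.80), CUP1-2 (1.69), YNL134C (1.65) and CUP1-1 (1.65) rose. CWP1 (-1.68 ± 0.17), ARG1 (-1.53 ± 0.15), NRG2 (-1.45), EXG1 (-1.43), LEU1 (-1.28), BAT1 (-1.27), ALD5 (-1.20) and ERG13 (-1.19) fell. Within carbon sources, a contrast chosen after seeing the data, 2328 genes changed in dextrose (1174 rose, 1154 fell), 3004 in ethanol (1285 rose, 1719 fell) and 3153 in galactose (1345 rose, 1808 fell). With quantile normalization these were 1526, 1683 and 1390, and the count over all cultures was 861, of which 194 were among the 462. The change differed from that in dextrose for 3204 genes in ethanol and 3249 in galactose. With each array centred, 54.5% rather than 35.9% of the genes called over all cultures were higher, and without any 1 of the 8 ethanol and galactose cultures between 179 and 213 genes were called.

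The order of enzymes in amino acid pathways was set against the time at which their genes reached the middle of their rise in cultures without amino acids. The mean of Spearman's rho was 0.21 over 11 pairs of pathway and culture, from 5 pathways and 4 cultures, with a permutation p of 0.333 (2-sided). Of the 46 times in dextrose cultures 40 lay before the first sample at 15 min, 22 of them at exactly 7.5 min, and were set by the straight line from the start. The mean rho of leucine (0.77), histidine (0.58) and arginine genes (-0.33), in the same 2 dextrose cultures, is therefore no observed order. It was 0.30 for methionine genes in 4 cultures, 2 of them in ethanol with all 12 times after the first sample, and -0.90 for lysine genes in 1 culture. These values are across genes, which are not independent replicates.

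Repeat arrays of the same culture and time differed by an SD of 0.16 log2 units across genes for SD+aa at 240 min, 0.20 for SEtOH+ino at 15 min and 0.68 for SEtOH+aa at 120 min. Pearson's r across genes was between 0.71 and 0.99 for the 6 pairs noted as technical replicates. A further 2 pairs, SD+ino at 240 min and Sgal+ino at 60 min, had SDs of 0.01, and their notes do not say that they were new hybridizations.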

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

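The tests of explanations, the splits of the cultures and the contrasts within a carbon source were chosen after the results were seen, while the interaction of carbon source and amino acids was planned. Some single cultures lay far from the others on the same carbon source. In SD+aa the arginine synthesis list had a median log2 ratio of -0.20 against 1.52 to 2.21 in the 4 other dextrose cultures, the unfolded protein response list 0.052 against -0.24 to -0.20, and 164 genes were at 2-fold or more at 15 min against 1360 to 1739. With ARNCQGKPSDEFTY, INO1 had a mean of -1.57 against -0.14 to 0.22, and the inositol and phospholipid list -0.24 against 0.10 to 0.21. The INO1 mean includes a value of -6.64 at 30 min, the lower limit of the table, with the other 4 times between -0.49 and -0.02. The galactose use list was at 0.88 in SEtOH+aa+ino against 0.55 to 0.60 in the other ethanol cultures. The phosphate response list was at -0.28 in Sgal+ino against -0.48 to -0.44, and the a-specific list at -0.14 in Sgal against -0.18 in the other galactose cultures. These are 8 of 108 groups. The cut used is nominally passed by chance in about 1 in 20 groups, a rate not tested here.

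The effect of amino acids differed between carbon sources for 1057 genes, between dextrose and ethanol for 974 and between dextrose and galactose for 1391. The change from 15 to 240 min in ethanol differed from that in dextrose for 3204 genes, and in galactose for 3249. Probes without a gene, used in no comparison of the report, also changed: 144 of 534 in ethanol against dextrose (against 31.0% of the genes), 176 of 534 in galactose against dextrose (33.0%, against 41.3%) and 308 of 448 against t = 0 (68.8%, against 74.5%).

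The stress response list had higher medians in ethanol and galactose than in dextrose, with 9 and 11 of 19 genes past the threshold and adjusted p = 0.416 and 0.703 with an estimated correlation. Values at the limit of the table did not make this pattern: with them missing, the 16 stress genes left in ethanol against dextrose had a median of 1.03 and a lower quartile of 0.50, and in galactose against dextrose 1.06 and 0.50. Filtering and washing, which the dextrose cultures had too, left the highest dextrose median at 0.67 at 120 and 240 min, under the lowest of the 8 other cultures (4.07). A response that builds up on the new carbon source may explain it and stays open: the list was higher at 240 than at 15 min in 8 of 8 ethanol and galactose cultures and in 0 of 5 dextrose cultures. With quantile normalization it was higher in 4 of those 8. That setting gives every array the same spread of ratios, so it cannot weigh against a response that grows in size. The bound of this test was revised after its result was seen.

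The galactose use genes GAL1, GAL7 and GAL10 did not pass between ethanol and galactose in the mean over time. An exchange of the 2 sets of media is argued against by the ethanol use list, whose 13 genes were higher in the cultures labelled ethanol by a median of 0.52 (lower quartile 0.35). Release from glucose repression without induction by galactose is a candidate explanation and stays open: 2 of 13 ethanol use genes were higher in galactose than in dextrose over all cultures, but 11 of 13 were with all amino acids present. Against it, GAL1 was lower in ethanol than in galactose at 240 min by -0.75 (adjusted p = 0.0494), though by -0.39 (adjusted p = 0.284) with quantile normalization. From 15 to 240 min GAL1 rose by 1.64 (95% interval 1.25 to 2.03) in galactose and 0.70 (0.31 to 1.09) in ethanol, a difference not tested. No other gene of the list passed at 240 min: GAL2 was at -0.98, GCY1 at -0.62, GAL10 at -0.35 and GAL7 at -0.11, but GAL3 at 0.61 and GAL80 at 0.20. A first form of the test of this explanation, revised after its result was seen, counted the missed threshold against it.

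Removal of amino acids moved synthesis genes mainly in dextrose. Whether the lone SD+aa culture made the pattern was not settled by a comparison that leaves it out. Against their own start, 86 amino acid synthesis genes had a median of 0.78 in the lower of the 2 dextrose cultures without amino acids. It was -0.01 in the highest of the 4 ethanol and galactose cultures without them. With all amino acids the median was -0.14 in SD+aa and between -0.54 and -0.35 in the ethanol and galactose cultures. Carbon sources thus differed with amino acids too, so that comparison does not isolate the amino acid effect. Ratios compressed by 1 factor are argued against in ethanol, where the effect as a share of that in dextrose had a lower quartile of 0.340 for sulfur and methionine genes and an upper quartile of 0.209 (median 0.128) for other synthesis genes, but cannot be told apart in galactose (0.132, and 0.283 with a median of 0.160). A later start in ethanol and galactose may contribute and stays open: the median effect at 15 min was 0.15 in both, and at 240 min 0.29 in ethanol and 0.48 in galactose (upper quartiles 1.12 and 0.89), against 1.30 and 0.80 in dextrose. The bound of this last test was revised after its result was seen, and a first test of compression by the spread of all genes was dropped because it turned with time (SDs in the 4 ethanol and galactose cultures of 0.36 to 0.49 at 15 min and 1.07 to 1.41 at 240 min, against 1.27 to 1.28 and 0.45 to 0.49 in the 2 dextrose cultures).

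Other splits of the cultures show whether another grouping gives as many genes, but they are too few to exclude chance. For ethanol against dextrose only the real split gave as many (1 of 35, 1662 genes, highest other 0). With 35 splits, 1 of 35 is the smallest share that can be reached. For galactose against dextrose the real split was also alone (1 of 35, 2212 genes, highest other 1370). For ethanol against galactose it was not (2 of 35, 201 genes, highest other 952). For amino acids the splits cannot decide (3 of 100, 14 genes, highest other 1131), since the count also follows other differences between the cultures. The 14 genes became 0 without SEtOH, SEtOH+aa, SEtOH+aa+ino or Sgal and 1 with quantile normalization. Neither can the splits decide for the interaction of amino acids with carbon source (3 of 97, 1057 genes, highest other 1315). With 0 genes every split gave as many for inositol (99 of 99, 0 genes, highest other 145) and its interaction with amino acids (94 of 94, 0 genes, highest other 401), so the splits tell nothing there. Under changes of sign only the real signs gave as many genes for the shifted cells (1 of 100, 3849 genes, highest other 2937). For 240 against 15 min the changes of sign cannot decide (3 of 100, 462 genes, highest other 2526). Only the real split gave as many for the change over time in ethanol (1 of 100, 3204 genes, highest other 2445) and galactose (1 of 100, 3249 genes, highest other 2969) minus dextrose. The split with 952 genes set the 4 ethanol and galactose cultures without amino acids against the 4 with them, that with 1131 set SD+aa, SD+ino and the 4 ethanol and galactose cultures with inositol against the other 5, and that with 2526 set SD, SD+aa and SD+ino against the other 10 cultures. Splits with several times the real count point to a structure of the cultures. The first resembles the interaction of carbon source and amino acids (1057 genes). The second, with inositol also a term of the fit, sets SD+aa alone apart from the other cultures. The last, apart from the 2 partial media placed with ethanol and galactose, resembles the difference in change over time between carbon sources (3204 and 3249 genes).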

How the results depend on the processing

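Values at the limit taken as missing, probes without a gene, the doubtful SEtOH+aa arrays, the fits of the partial media with 1 mean per carbon source and amino acid setting, and all alternatives of the contrasts within a carbon source or amino acid setting were chosen after seeing the data, the others were planned. Counts stayed within 1.5 times the reported one in 26 of 26 comparisons with each array centred, with probes without a gene included and with the doubtful arrays left out, and in 10 of 10 with first arrays of repeats. For the counts below the cause was not tested unless stated.

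With genes that had a value on every array, and so fewer genes tested, the counts were 903 for ethanol and 1217 for galactose against dextrose, 107 for ethanol against galactose, 5 for amino acids, 70, 63 and 5 for LIVWHM against ARNCQGKPSDEFTY and each against none, and 2245 against t = 0. A further 2-fold threshold, stricter by construction, gave 376, 597 and 35 for the carbon sources, 53 for 240 against 15 min and 677 against t = 0. Quantile normalization gave 127 for ethanol against galactose, 1 for amino acids, 4 for amino acids in galactose and 861 for 240 against 15 min. Within dextrose, ethanol and galactose the change over time had 1526, 1683 and 1390 genes, and 1970 and 1769 differed from dextrose. With trend and robust the counts were 396 for ethanol against galactose, 23 for amino acids, 35 for ARNCQGKPSDEFTY against none and 195 for 240 against 15 min. At 15 and 30 min they were 0 for ethanol against galactose, 0 for amino acids and 55 for ARNCQGKPSDEFTY against none. At 120 and 240 min they were 3167 for ethanol against dextrose, 741 for ethanol against galactose, and 50, 58 and 1 for the partial media. With 9 cultures 2 genes passed for ethanol against galactose and 0 for amino acids, and with culture as a random block 857 and 227. With values at the limit missing, 40, 34 and 0 passed for the partial media and 26 for amino acids in galactose. With 1 mean per carbon source and amino acid setting, in place of 1 amino acid effect for all carbon sources, the partial media had 310, 374 and 188 genes, 204, 291 and 170 with values at the limit missing and 441, 530 and 506 with quantile normalization.

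Leaving out each culture in turn, the lone culture left in an arm being assumed to vary like the others, gave 979 to 2003 genes for ethanol and 1432 to 2646 for galactose against dextrose, 2 to 852 for ethanol against galactose, 0 to 78 for amino acids and 0 to 0 for inositol. It gave 102 to 308, 70 to 384 and 0 to 202 for the partial media in the order above, 179 to 681 for 240 against 15 min and 3691 to 4025 against t = 0. The ranges were 677 to 1396 for the interaction of carbon source with amino acids and 0 to 18 for that of inositol with amino acids. For amino acids in dextrose, ethanol and galactose they were 983 to 1595, 13 to 46 and 0 to 506, and 659 to 1156 and 817 to 1648 for the difference of dextrose from ethanol and galactose. Without amino acids they were 741 to 2096 for ethanol and 1680 to 2787 for galactose against dextrose, and with all of them 1423 to 2634 and 2469 to 2739. The change over time had 1728 to 2545 genes in dextrose, 2624 to 3210 in ethanol and 2832 to 3367 in galactose, and its difference from dextrose 3000 to 3359 and 3102 to 3409.

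Values of the genes named in the text kept their direction and side of the threshold in 3117 of 3530 cases, and 2 reversed: in ethanol against dextrose at 15 and 30 min, ACS1 was at -0.060 and JEN1 at -0.60 (adjusted p = 0.783 and 0.145), and the cause was not tested. Of the list tests in the 10 planned comparisons, 106 of 264 passed, 104 with each array centred, 98 with quantile normalization and 0 with an estimated correlation. Over all comparisons 11 lists reversed, each with quantile normalization, and the cause was not tested. The stress response list was at -0.71 over all cultures (adjusted p = 0.00286, a pass in the other direction), -0.14 in ethanol and -0.32 in galactose for 240 against 15 min (adjusted p = 0.822 and 0.839), at 0.092 for amino acids in dextrose, and at 0.17 and -0.12 for the difference of that effect from ethanol and galactose. The arginine list was at 0.054 and the branched-chain list at -0.069 for 240 against 15 min over all cultures, and the arginine list at -0.15 in dextrose. With all amino acids the nitrogen catabolite repressed list was at -0.21 in ethanol and -0.24 in galactose against dextrose.

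Centring moved the median of all genes for ethanol against dextrose from -0.07 to 0.04. Of the counts at single time points 86 of 90 stayed within 1.5 times: amino acids at 240 min had 8 genes with each array centred and 8 with values at the limit missing, and amino acids in galactose 1 at 15 min and 49 at 240 min with those values missing. The mean rho of pathway timing was between 0.08 and 0.33 under every alternative run, with no pass. What signal over background limits was not analysed here, since intensities were not used.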

Other observations

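The tests of the hypotheses below, and the contrasts with and without amino acids, were chosen after the results were seen. Without amino acids, all 6 arginine genes tested (6 adjusted over the list alone) and all 8 purine genes (8 adjusted over the list alone) were lower in ethanol than in dextrose. The median log2 differences were -1.98 for each, in 2 cultures against 2. ARG1 was higher without than with all amino acids by 2.75 in dextrose and 0.19 in ethanol, and ADE2 by 1.79 and 0.17. With all amino acids, in 2 cultures against 1, 1 of 6 arginine genes (0 adjusted over the list alone) and 2 of 8 purine genes (0 adjusted over the list alone) were lower. Stress response genes were higher in ethanol in 7 of 19 cases and lower in 1 without amino acids (7 and 1 adjusted over the list alone), and higher in 17 of 19 with them (18 adjusted over the list alone). In limma 1735 genes differed between ethanol and dextrose without amino acids and 2237 with them, and 2450 and 2758 between galactose and dextrose. For ethanol without amino acids the count was 862 without SD, 1120 without SD+ino, 741 without SEtOH and 939 without SEtOH+ino, and with all amino acids it was 1423 without SEtOH+aa+ino. The difference between the 2 settings, which is the same as the amino acid effect in dextrose minus that in ethanol, passed for 5 of 6 arginine genes (5 adjusted over the list alone), 7 of 8 purine genes (8 adjusted over the list alone) and 12 of 19 stress response genes (12 adjusted over the list alone). Its medians were 1.84, 1.51 and 1.17, with camera adjusted p values of 2.78e-06, 4.06e-07 and 1.36e-06 that became 0.147, 0.147 and 0.336 with an estimated correlation. For the stress response list it was 0.17 (adjusted p = 0.515) with quantile normalization. The dextrose arm with all amino acids was 1 culture, whose own variation was not measured.

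A hypothesis was that the genes lower with ARNCQGKPSDEFTY than without amino acids come from single values at the limit of the table. Each of the 10 lower genes had 1 such value in that culture. With those values taken as missing, 8 were still tested and had a median difference of -0.19 (from -0.28 to 0.05) in place of -1.53, so they may stem from such values. Of the 2 higher genes, NFG1 was no longer tested, and ARO10, with no value at the limit, stayed at 3.71 ± 0.53 but had an adjusted p of 0.285. The bound for this test was set after its values were seen, and it covers these genes only: with 1 mean per carbon source and amino acid setting, 77 genes were lower, and 50 with the values at the limit missing. A second hypothesis was that methionine is the amino acid that sets the sulfur and methionine genes. With LIVWHM, which holds methionine, the 20 genes were lower than with ARNCQGKPSDEFTY, which does not, by a median of -4.20 and an upper quartile of -3.53. Methionine may thus set these genes, though the 2 media also differ in the other amino acids, and each was 1 culture whose own variation was not measured.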
